A study of Mus musculus with 2 samples.

How the data were processed

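Small RNA was measured by microRNA-seq in heart tissue of adult male mice of the strain 5xFAD/CAST, aged 8 to 10 months. 5xFAD is a transgenic mouse model of amyloid deposition in the brain, and CAST is a wild-derived inbred mouse strain. The labels put both libraries in a single group, as biological replicates 1 and 2, so no comparison between conditions was possible. The labels give the replicates different biosample entries and the same donor entry, and do not say that they came from separate animals. All p-values and spreads between the replicates therefore measure only the difference between these libraries, which may be technical.

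Per the labels, total RNA was used and the size range was below 30. Each deposited table holds raw read counts for 2202 miRNA genes in 3 columns, with 4 leading summary lines that name no gene. The first of the 3 deposited count columns ignores strand, and the other 2 hold a strand each, as judged from their layout and values. Genome build mm10 and the gene annotation GENCODE M21 are named in the description files deposited with the counts. The aligner, its version and any read filter are not given in the sources used here. The counts are not normalized, and reads that aligned to several places were counted in a summary line and given to no gene. A miRNA gene here is the annotated hairpin, so the mature arms of a hairpin were not told apart.

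The strand column with the larger total in both libraries was taken as the sense strand, by a rule set before the data were examined. Sense counts summed to 3889280 in replicate 1 and 5058613 in replicate 2. These were 35.9% and 35.6% of the 10824381 and 14212392 reads in the deposited tables. The summary lines held 42.3% and 46.8% of reads as aligned to several places. They held 14.5% and 12.5% as unmapped and 7.33% and 5.15% as aligned outside miRNA genes. The summary lines stayed out of library sizes and tests. In the column that ignores strand, 857957 and 1274429 reads were set aside as ambiguous, and the gene sums were 22.1% and 25.2% lower than in the sense column. In the sense column 0 reads were ambiguous.

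All 2202 gene identifiers matched GENCODE M21, which supplied names, coordinates, host genes and hairpin sequences. Levels are CPM, each deposited sense count scaled by its library's sense total, given as mean ± SD of the libraries. A gene was called detected with at least 10 counts in both libraries and tested with a sum of at least 10. Shares of a single library carry 95% Clopper-Pearson intervals. A count of 0 allows up to 3 counts, which is 0.771 CPM in replicate 1 and 0.593 CPM in replicate 2. The reads come from PCR with no molecular identifiers recorded in the sources used here, so intervals and floors cover counting error only.

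Differences between the libraries were tested per gene with a two-sided exact binomial test at the ratio of effective library sizes. Effective sizes came from TMM normalization in edgeR 4.0.16, and p-values were Benjamini-Hochberg adjusted over the tested genes at 0.05. Higher and lower refer to genes past this test. The quasi-likelihood test needs a second group and was not run. Log2 ratios are replicate 2 over replicate 1 after TMM scaling, with 1 CPM added to both levels, which understates the ratio of low genes. The biological coefficient of variation was the common dispersion of edgeR with an intercept-only design. A test on the reads of 2 libraries compares those libraries, not conditions.

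18 miRNA lists were fixed before the data were examined: cardiac muscle, skeletal muscle, endothelial, smooth muscle, fibroblast, erythroid, leukocyte, neuronal, epithelial, liver and gut, pancreas, stem cell, testis X-linked, let-7 family, miR-30 family, miR-17-92 cluster and paralogs, Dlk1-Dio3 imprinted cluster, and cardiac stress. Of the 181 entries, 177 matched by symbol and 4 through an older symbol. Each list's median level was placed among 10000 random lists of the same size drawn from detected genes. Each list's median log2 ratio was placed among 10000 random lists of the same size matched on mean level, each member replaced by a gene from the 40 nearest in level. These percentiles describe these libraries and are not tests on replicates.

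Clusters were detected genes on the same strand with gaps of at most 10 kb. Their shared variation was the intraclass correlation of log2 ratios, with a one-sided permutation test over 100000 permutations. The level of genes with a same-sequence copy by name was compared with that of other list genes by a two-sided permutation test. Genes are not independent replicates in either test.

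Genes were named by a rule set before the data were examined. It takes the 20 genes of highest mean CPM, all members of the cardiac muscle, skeletal muscle, endothelial, smooth muscle, erythroid and leukocyte lists, and the 3 most abundant members of each other list. It also takes the 5 largest and 5 smallest log2 ratios among genes past the test with a mean of at least 100 CPM, Mir208a and Mir208b, the 5 genes with the most opposite-strand counts, and members of the 3 largest clusters as groups. Every other gene named was chosen after its values were seen: Mir302c, Mir367, Mir200a, Mir205, Mir29c, Mir195a, Mir194-2, Mir30c-2, Mirlet7e, Mir141 and Mir429.

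Alternatives set before the data were examined covered total-count scaling, DESeq2 1.42.0 size factors and dispersion trend, other count minimums and pseudocounts, the column that ignores strand, each replicate left out, other cluster gaps and other gene sets. Alternatives added after seeing the data were copies defined by a shared stretch of at least 20 nt, removal of a straight-line GC trend, and clusters without the Mir302 genes. Computation used R 4.3.3, Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.

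The methods were tested on simulated data. In Poisson libraries with the real means and sizes, 404 genes were tested and 2.78% of the 216 unchanged genes were called. Changes of 1.2-fold, 1.5-fold, 2-fold and 4-fold were called in the right direction for 26.5%, 64%, 78.3% and 93.0% of changed genes. These libraries held no variation beyond counting error, while the real pair had a coefficient of variation of 0.357. The rates of calls therefore do not carry over to the real pair. A coefficient of variation simulated at 0.3 was recovered as 0.293 over 403 genes. An intraclass correlation simulated at 0.5 was recovered as 0.499 over 211 genes, averaged over repeated draws.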

Results

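Heart tissue of adult male 5xFAD/CAST mice was profiled by microRNA-seq in 2 libraries of a single group, replicates 1 and 2. The tables held 3889280 and 5058613 sense counts over 2202 annotated miRNA genes. The design implied a description of the heart miRNA profile, its counts in cell-type lists, and the agreement between the libraries. All values with an SD have n = 2.

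Among reads given to a gene, the heart profile was led by Mir378a, a hairpin in an intron of the mitochondrial regulator gene Ppargc1b, at 124376 ± 25707 CPM (SD, n = 2). Mir126a, a hairpin within the endothelial gene Egfl7, followed at 87451 ± 476 CPM. The let-7 members Mirlet7g, Mirlet7b, Mirlet7i and Mirlet7d stood at 71319 ± 2977, 61720 ± 2076, 61595 ± 2389 and 52948 ± 3452 CPM. Mir22, an abundant miRNA of heart muscle, stood at 61609 ± 29097 CPM, with 41035 CPM in replicate 1 and 82183 CPM in replicate 2. The 10 most abundant genes took 64.2% of sense counts in replicate 1 (95% Clopper-Pearson interval 64.1 to 64.2) and 67.9% in replicate 2 (67.8 to 67.9), a mean of 66.0% ± 2.62. Reads aligned to several places, which were given to no gene, outnumbered the sense counts by 1.18 to 1 and 1.31 to 1, so these ranks hold only among reads given to a gene.

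The other 3 of these 10 were Mir23b at 54033 ± 7153 CPM, Mir23a at 45902 ± 14757 CPM and Mir99a at 39168 ± 7027 CPM. Ranks 11 to 20 were held by Mir139, Mir149, Mir143, Mir26b, Mir29a, Mir30a, Mir30d, Mir34a, Mir191 and Mir125a, from 37568 ± 7051 CPM for Mir139 to 7879 ± 2449 CPM for Mir125a. The 20 genes together took 85.2% ± 0.510 of sense counts. On mm10, Mir378a (ENSMUSG00000105200.1) lies on chromosome 18 from 61397835 to 61397900. Mir126a (ENSMUSG00000065540.1) lies on chromosome 2 from 26591357 to 26591429. In all, 325 genes were detected in both libraries, 341 in replicate 1 and 343 in replicate 2, and 1490 genes had 0 counts in both. With a minimum of 1 count in both libraries, 538 genes were counted as detected.

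**Figure D1:**
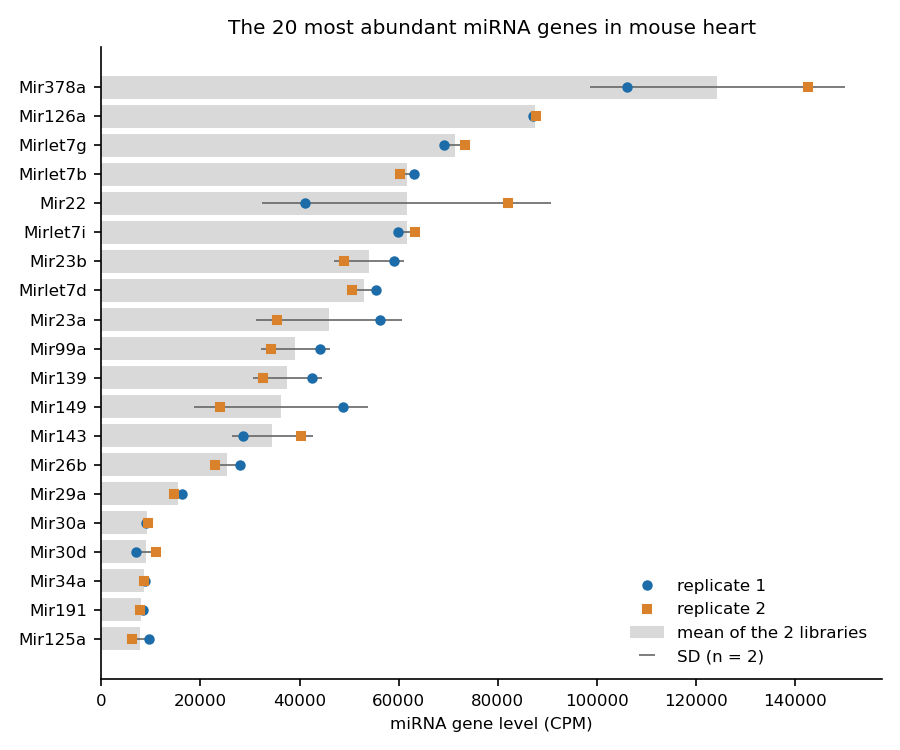
Levels of the 20 most abundant miRNA genes, in CPM, with bars for the mean, lines for the SD (n = 2) and points for each library. Mir378a leads at 124376 CPM, and Mir22 differs between replicates 1 and 2 (41035 and 82183 CPM) more than Mir126a does (87115 and 87787 CPM).

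Genes that share a stretch of at least 20 nt with another hairpin may lose reads to the class given to no gene, so their levels and ratios are uncertain throughout. Those named here are Mir378a, Mir23a, Mir23b, Mir1a-1, Mir1a-2, Mir133a-1, Mir133a-2, Mir133b, Mir146, Mir128-1, Mir219a-1, Mir92-1, Mir411, Mir26a-2, Mir181b-2, Mir302a, Mir302b, Mir29c, Mir194-2, Mir30c-2, Mirlet7c-2, Mir27b, Mir24-1, Mirlet7f-1 and Mirlet7a-1. By list they are 10 of 11 neuronal, 6 of 9 fibroblast, 6 of 12 let-7, 4 of 8 cardiac muscle, 1 of 2 skeletal muscle, 2 of 5 liver and gut, 2 of 6 miR-30, 4 of 14 stem cell, 4 of 15 miR-17-92, 3 of 12 cardiac stress, 1 of 6 leukocyte, 5 of 48 Dlk1-Dio3, 1 of 12 testis X-linked and 0 in the other lists.

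The cardiac muscle list held 0.713% ± 0.050 of sense counts, nearly all of it from Mir499 and Mir208a, which lie in introns of the myosin heavy chain genes Myh7b and Myh6. Mir499 stood at 4310 ± 2232 CPM and Mir208a at 2685 ± 1697 CPM. Mir208b, in an intron of the slow myosin gene Myh7, stood at 85.6 ± 41.1 CPM. Of the hairpins of the muscle miRNAs miR-1 and miR-133, Mir1a-2 stood at 40.1 ± 5.40 CPM, at percentile 46.2 of detected genes. The others lay near the minimum of 10 counts, with Mir133a-1 at 3.58 ± 0.029, Mir133a-2 at 2.67 ± 0.139, Mir1a-1 at 1.65 ± 0.937 and Mir1b at 1.21 ± 0.251 CPM. Mir1a-1, Mir1a-2, Mir133a-1 and Mir133a-2 together had 174 counts in replicate 1 and 259 in replicate 2. Of the 8 members 6 were detected, and the median level of those 6 lay at percentile 53.6 of random lists.

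Mir208a exceeded Mir208b in both libraries. The ratio of their counts was 33.9 in replicate 1 (95% exact interval 30.8 to 37.3) and 26.3 in replicate 2 (23.3 to 29.7), a mean of 30.1 ± 5.38. Mir208a (chromosome 14, 54949060 to 54949142) and Mir208b (chromosome 14, 54975700 to 54975776) carry the miRNAs of the myosin genes Myh6 and Myh7, of which Myh6 is the main form of the adult mouse ventricle.

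Among the other cell types of heart tissue, the endothelial list was the most abundant, at 8.75% ± 0.048 of sense counts, from Mir126a alone. Mir126b, annotated on the other strand of Mir126a, had 6 and 4 sense counts. The smooth muscle list held 3.59% ± 0.821, from Mir143 at 34450 ± 8168 CPM and Mir145a at 1493 ± 41.8 CPM, while Mir145b had 1 and 3 counts. The fibroblast list held 2.19% ± 0.150, led by Mir29a at 15542 ± 1150 CPM, Mir21a at 3462 ± 3070 CPM and Mir214 at 1926 ± 950 CPM. The fibroblast genes Mir21a and Mir29a are also expressed by other cells.

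Blood cell lists were lower than the endothelial, smooth muscle and fibroblast lists. The leukocyte list exceeded the cardiac muscle list in replicate 1 (0.838% against 0.678%) but not in replicate 2 (0.680% against 0.748%). In the cardiac muscle list 4 of 8 members share a stretch with another hairpin, so its share may be understated. List shares are not shares of cells. The leukocyte list held 0.759% ± 0.112 of sense counts, from Mir155 at 4042 ± 1175 CPM, Mir146 at 1674 ± 173 CPM, Mir150 at 1591 ± 115 CPM, Mir223 at 187 ± 5.04 CPM and Mir142 at 95.1 ± 0.749 CPM. Mir142b had 0 counts. The leukocyte share thus rests mainly on Mir155, Mir146 and Mir150, whose cell source in this tissue was not tested. The erythroid list held 0.148% ± 0.030, mostly from Mir486 at 1180 ± 218 CPM, with Mir451a at 226 ± 87.0 CPM, Mir144 at 42.3 ± 14.3 CPM and Mir3107 at 29.5 ± 6.71 CPM. Its share thus rests mainly on Mir486, whose cell source in this tissue was not tested. Mir451b had 0 counts.

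miRNA genes of tissues other than heart held small shares of sense counts. The stem cell list held 0.0622% ± 0.0582, nearly all from Mir302 genes, with 817 counts in replicate 1 and 5227 in replicate 2, against 970 and 901 for the neuronal list. The skeletal muscle list held 0.0018% ± 0.00014, with Mir206 at 13.3 ± 2.30 CPM and Mir133b at 4.50 ± 0.907 CPM. The neuronal list held 0.0214% ± 0.0050, mostly Mir128-1 at 174 ± 45.2 CPM, followed by Mir137 at 15.6 ± 2.48 CPM and Mir219a-1 at 12.8 ± 5.53 CPM. The neuronal share may be understated, since 10 of the 11 members share a stretch with another hairpin. The epithelial list held 0.0266% ± 0.0115, led by Mir203 at 119 ± 49.8 CPM, Mir200c at 91.6 ± 27.0 CPM and Mir200b at 26.5 ± 24.8 CPM. The liver and gut list held 0.0130% ± 0.0023, with Mir215 at 42.5 ± 17.1 CPM, the hepatocyte miRNA gene Mir122 at 27.9 ± 1.21 CPM and Mir192 at 25.5 ± 0.816 CPM. The pancreas list held 0.0030% ± 0.0014, with Mir375 at 29.3 ± 14.5 CPM, 4 counts in each library for Mir217 and 1 and 0 for Mir216a. The testis X-linked list had 3 and 6 counts, among them 2 and 2 for Mir470, 0 and 4 for Mir741, and 1 and 0 for Mir743.

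Of the miRNA families, let-7 held 26.5% ± 0.0091 of sense counts with 12 of 12 members detected, and its median level lay at percentile 100 of random lists. The miR-30 family held 2.70% ± 0.0046 with 6 of 6 detected, led by Mir30a at 9232 ± 187 CPM, Mir30d at 9016 ± 2815 CPM and Mir30e at 6618 ± 2970 CPM. The cardiac stress list, which shares 3 of its 12 members with other lists, held 6.09% ± 1.09, mostly from Mir23a, Mir34a at 8678 ± 98.5 CPM and Mir21a. The miR-17-92 cluster and paralogs held 0.609% ± 0.093, led by Mir93 at 2469 ± 317 CPM, Mir92-1 at 1137 ± 468 CPM and Mir17 at 891 ± 55.6 CPM. The Dlk1-Dio3 imprinted cluster held 0.149% ± 0.010, with 28 of 48 members detected and its median level at percentile 2.19, led by Mir127 at 498 ± 156 CPM, Mir411 at 196 ± 37.4 CPM and Mir541 at 159 ± 32.3 CPM.

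**Figure D2:**
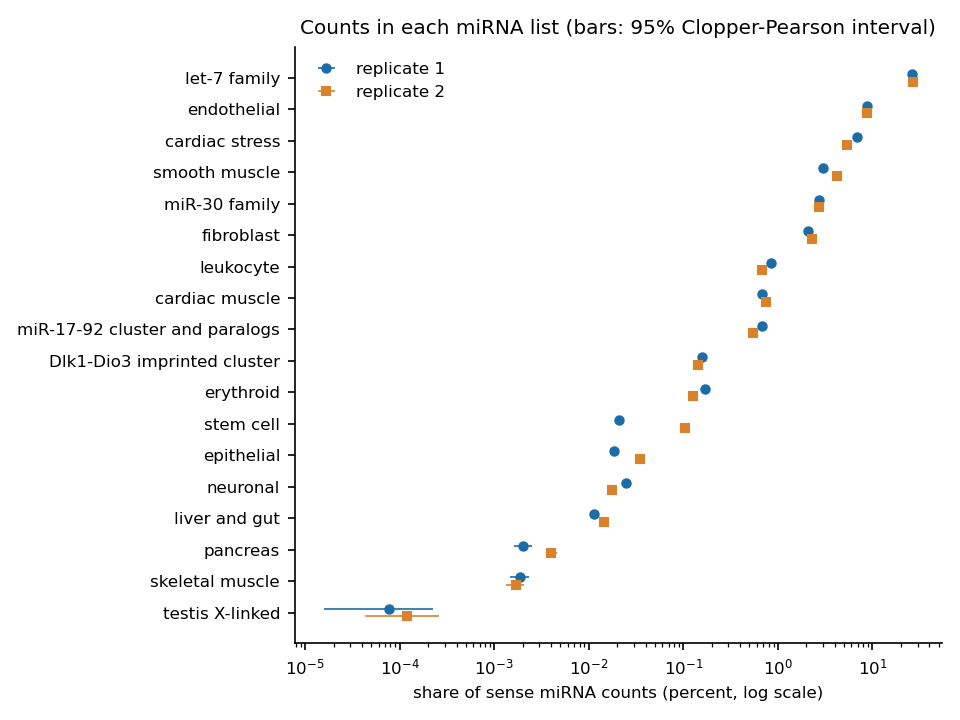
Share of sense counts in each fixed miRNA list, in percent on a log axis, for replicates 1 and 2, with 95% Clopper-Pearson intervals as lines. The let-7 family leads at 26.5% and the testis X-linked list had 3 and 6 counts. The stem cell list parts the libraries, at 0.0210% in replicate 1 and 0.103% in replicate 2.

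Counts on the opposite strand came almost wholly from genes annotated on both strands of the same hairpin. The opposite strand held 18.1% of strand-specific counts in replicate 1 (18.0 to 18.1) and 20.1% in replicate 2 (20.1 to 20.2), a mean of 19.1% ± 1.45. The 5 genes with the most such counts were Gm25301, opposite Mir378a, Mir126b, opposite Mir126a, Gm24083, opposite Mir191, Mir30f, opposite Mir30e, and Gm25927, opposite Mirlet7e. Opposite-strand counts of Gm25301, 413035 and 721126, equalled the sense counts of Mir378a. Without Gm25301 the share was 10.1%. At genes with no miRNA gene annotated opposite, 107 and 109 opposite-strand counts remained, or 0.0035% and 0.0029%.

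The libraries ranked the miRNA genes alike, while single genes differed between them. Across the 325 detected genes, log2(CPM + 1) correlated with Pearson r = 0.980 and Spearman rho = 0.969. These are correlations across genes, which are not independent replicates. By the exact binomial test, which covers counting error only, 187 of 412 tested genes differed, 93 higher in replicate 2 and 94 higher in replicate 1. Of these, 49 differed at least 2-fold, 31 higher in replicate 2 and 18 higher in replicate 1. Replicate 2 held the higher level in 49.7% of the 187 calls and 63.3% of the 49, against 39.7% and 49.1% with total-count scaling. Among detected genes 69.8% lay within 1.5-fold, and the biological coefficient of variation was 0.357. Calls rose with depth: 53 of 57 genes with a mean of at least 5000 counts were called. Of the 70 genes with a mean of 5 to below 10 counts, 4 were called. The number of called members in a list therefore depends on how abundant its members are.

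Among genes of at least 100 CPM, Mir26a-2 and Mir185 stood farthest apart. Mir26a-2 was 9.68-fold higher in replicate 2, with 33.7 CPM in replicate 1 and 308 CPM in replicate 2. Mir185 was 9.32-fold higher in replicate 1, with 2330 and 229 CPM. Mir21a, which rises in many tissues under stress, was 4.74-fold higher in replicate 2, with 1291 and 5632 CPM. The heart muscle gene Mir208a was 2.40-fold higher in replicate 1 and Mir499 2.34-fold higher in replicate 2. Mir423, Mir99b and Mir181b-2 were 2.43-fold, 2.39-fold and 2.37-fold higher in replicate 1. Mir22 was 2.18-fold higher in replicate 2.

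**Figure D3:**
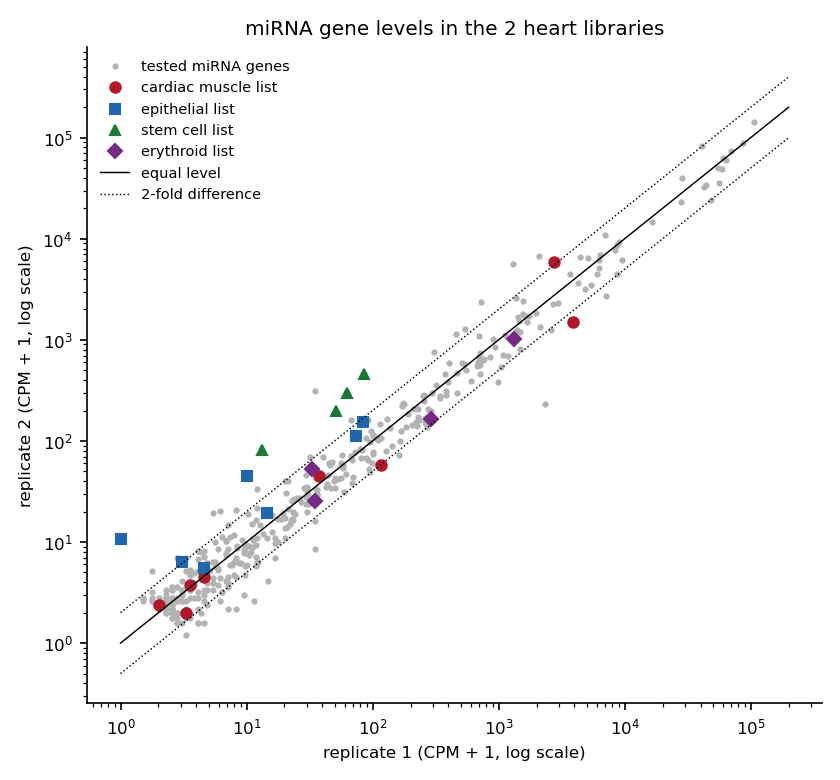
Level of each tested miRNA gene in replicate 1 (horizontal) and replicate 2 (vertical), as CPM + 1 on log axes, with 4 fixed lists coloured. The solid line marks equal level and the dotted lines a 2-fold difference. Mir302 genes of the stem cell list lie above the upper dotted line.

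The Mir302 genes and 5 of 7 tested epithelial genes were higher in replicate 2. The 4 tested members of the 14 in the stem cell list, all from a single cluster, Mir302a, Mir302b, Mir302c and Mir302d, which pluripotent cells express, were higher in replicate 2, by 5.84-fold, 5.08-fold, 6.60-fold and 4.17-fold. Adjusted over the list alone, 4 were called. The list's median log2 ratio was 2.45, at percentile 100 of matched random lists. Mir302a stood at 84.8 and 461 CPM, Mir302b at 62.2 and 295 CPM, and Mir302d at 50.4 and 196 CPM. The neighbouring Mir367 had 0 counts in both libraries, which allows up to 0.771 and 0.593 CPM.

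Of the 7 tested epithelial genes 5 were higher in replicate 2 and 0 in replicate 1, with 6 called when adjusted over the list alone. The epithelial median log2 ratio was 0.99, at percentile 99.9. The random lists drew each gene on its own, while several epithelial genes are neighbours. Mir141 and Mir200c lie in a cluster on chromosome 6, and Mir429 and Mir200b in another on chromosome 4. The members are therefore not independent draws. Mir200b was 4.88-fold higher with 35 and 223 counts, Mir203 1.99-fold and Mir200c 1.65-fold higher. Mir205, an epithelial miRNA gene, had 0 counts in replicate 1 and 49 in replicate 2, at least 13.7-fold higher against the floor of 3 counts in replicate 1. Mir200a also differed, with 8 and 27 counts, while Mir141 (14 and 23 counts) and Mir429 (53 and 94 counts) did not pass the test. The pancreatic gene Mir375 was 2.19-fold higher in replicate 2, the only tested member of its list, with 1 called when adjusted over the list alone.

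Lists of heart cell types went both ways. Of 17 lists with tested genes, 8 kept the direction of their median under every other setting that filtered low counts. They were smooth muscle, neuronal, epithelial, liver and gut, pancreas, stem cell, miR-30 and cardiac stress. The other 9 changed direction under at least 1 such setting, so their medians below have no settled direction. With no low-count filter the pancreas median was -0.12, against 1.13 in the main setting, so the direction of the pancreas list is not settled either. A kept direction does not show that a list moved, since every setting reuses the same libraries. The miR-30 median was only 0.020 with total counts. The smooth muscle, liver and gut and miR-30 medians lay at percentiles 76.9, 70.4 and 78.1 of matched random lists. In the cardiac muscle list 2 members were higher in each library, with 4 called when adjusted over the list alone, and the median log2 ratio of 0.12 lay at percentile 71.5. It was -0.27 with a sum of at least 50 counts and -0.29 in the column that ignores strand. Mir1a-2 was 1.31-fold higher in replicate 2, a call that total-count scaling did not give (adjusted p = 0.148, exact binomial test). Of the smooth muscle genes Mir143 was 1.53-fold and Mir145a 1.13-fold higher in replicate 2, with 2 called when adjusted over the list alone and the median log2 ratio of 0.39 at percentile 76.9. Of the tested fibroblast genes Mir21a and Mir29c were higher in replicate 2 and Mir214 and Mir29a in replicate 1, with 4 called when adjusted over the list alone and a median of 0.16 at percentile 78.2. Mir29a changed direction in the column that ignores strand, where its log2 ratio was 0.018 against -0.03. Of the endothelial genes Mir126a was 1.10-fold higher in replicate 2, with 1 called when adjusted over the list alone and a median of -0.16 at percentile 32.3, which was 0.11 with a sum of at least 50 counts, where Mir126b is not tested. Of the 2 skeletal muscle genes 0 were called in either count, with a median of 0.11 at percentile 54.2, which was -0.24 with a sum of at least 50 counts.

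Of the erythroid genes Mir451a was 1.60-fold higher in replicate 1, Mir486 was higher there with 1334 and 1026 CPM, and Mir144 was 1.75-fold higher in replicate 2, with 3 called when adjusted over the list alone. Their median log2 ratio was -0.30, at percentile 8.68. Of the leukocyte genes Mir155 was 1.40-fold higher in replicate 1 and Mir146 1.26-fold higher in replicate 2, with 2 called when adjusted over the list alone and a median of 0.066 at percentile 58.1. In the neuronal list 2 genes, Mir128-1 and Mir219a-1, were higher in replicate 1, with 2 called when adjusted over the list alone and a median of -0.41 at percentile 9.88. In the liver and gut list Mir215 and Mir194-2 were higher in replicate 2, with 2 called when adjusted over the list alone and a median of 0.18 at percentile 70.4. None of the testis X-linked genes reached a sum of 10 counts.

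Among the families, 7 let-7 genes were higher in replicate 2 and 2 in replicate 1, 0 of them by 2-fold or more. When adjusted over the list alone 9 were called, and the median log2 ratio was 0.12 at percentile 81.6. With total-count scaling 4 were higher in replicate 2 and 5 in replicate 1, Mirlet7b changing direction. Total-count scaling moved the median of all detected genes by -0.12 on the log2 scale. Of the miR-30 genes 3 were higher in replicate 2, among them Mir30d (1.70-fold), and 2 in replicate 1, Mir30e (1.77-fold) and Mir30c-2, with 6 called when adjusted over the list alone and a median of 0.14 at percentile 78.1. The miR-17-92 list had 3 higher in replicate 2 and 5 in replicate 1, with 8 called when adjusted over the list alone and a median of -0.031 at percentile 44.9. The Dlk1-Dio3 list had 6 and 5 of 40 tested, with 11 called when adjusted over the list alone and a median of 0.093 at percentile 88.7. The cardiac stress list had 7 higher in replicate 2, among them Mir21a and Mir195a, and 3 in replicate 1, among them Mir23a, with 10 called when adjusted over the list alone and a median of 0.24 at percentile 93.5.

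**Figure D4:**
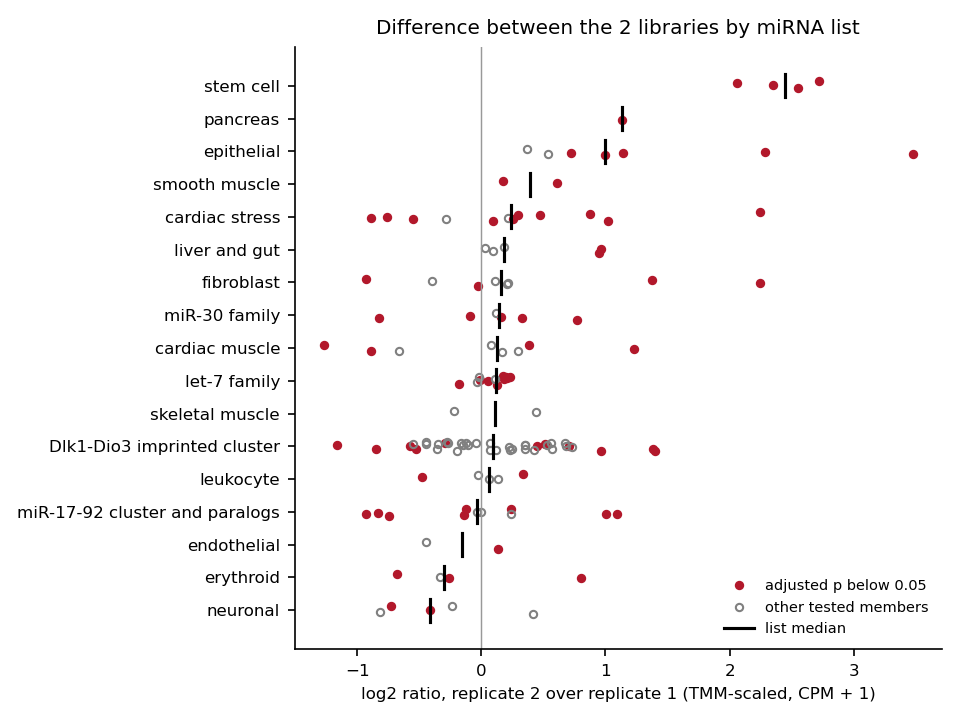
Log2 ratio of replicate 2 over replicate 1 for each tested member of the fixed lists, after TMM scaling with 1 CPM added. Filled points passed the exact binomial test, open points did not, and vertical bars mark list medians, with the stem cell list at 2.45 and the epithelial list at 0.99.

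Neighbouring miRNA genes shared part of their difference between the libraries. The largest clusters by counts were Mirlet7c-2 and Mirlet7b on chromosome 15, the Mir23b, Mir27b and Mir24-1 genes on chromosome 13, and Mirlet7d, Mirlet7f-1 and Mirlet7a-1 on chromosome 13. Their median log2 ratios were 0.0073, 0.30 and 0.11. Over 45 clusters of 133 genes the intraclass correlation of log2 ratios was 0.43 (one-sided permutation p = 2e-05). In 16 of the 45 clusters the log2 ratios spanned more than 1. Without the Mir302 genes, a setting added after seeing the data, it was 0.19 (permutation p = 0.0237).

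List genes with a same-sequence copy by name did not differ detectably in level from the others. The 33 genes with a copy had a median log2(CPM + 1) of 4.08 and the other 145 a median of 3.84, a difference of 0.24 (two-sided permutation p = 0.860). The difference was -0.45 in the column that ignores strand (permutation p = 0.721).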

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

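The test of heart muscle RNA below, with its bound, was chosen after the levels were seen. Values outside the gene counts stood above the limit that a count of 0 allows. Reads aligned to several places were 42.3% of reads in replicate 1 and 46.8% in replicate 2. Reads aligned outside miRNA genes were 7.33% and 5.15%. Mir122, which has no miRNA gene annotated opposite, had 62 and 43 opposite-strand counts beside 112 and 137 sense counts.

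In these heart libraries Mir1a-1, Mir133a-1 and Mir133a-2 lay near the minimum of 10 counts, and Mir1a-2 at percentile 46.2 of detected genes. Reads aligned to several places were given to no gene, and each of these 4 hairpins shares a stretch with another. If such a loss set their levels, other list genes with a shared stretch should lie lower. Their median log2(CPM + 1) differed by +0.323 from that of list genes without such a stretch (two-sided permutation p = 0.758). That test compares different genes, each with a level of its own, so it cannot show whether copies lost reads. If the tissue held little heart muscle RNA, Mir208a and Mir499 should lie below the median of detected genes, and the lowest of their percentiles in either library was 85.5. That is above the median, so the level expected with little heart muscle RNA was not seen. It is short of the percentile of 90 set as the bound for excluding this explanation. Neither explanation was excluded and both remain open. No biological explanation was tested, since the design has a single group.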

How the results depend on the processing

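No paired analysis was possible because the design has a single group. The alternative with the GC trend removed and that without the Mir302 genes were chosen after seeing the data. Under the alternatives run for them, the number of genes that differ (174 to 199 against 187) and that of 2-fold differences (34 to 56 against 49) stayed within 1.5 times, as did the coefficient of variation (0.263 to 0.367). The cluster correlation stayed past its threshold (0.195 to 0.483). The balance of calls was less stable: replicate 2 was higher in 39.7% (total counts) to 55.7% (column that ignores strand) of the calls against 49.7%, and in 49.1% (total counts) to 70.6% (sum of at least 50) of the 2-fold calls against 63.3%. With each replicate left out, the detected genes numbered 341 to 343, the share of the 10 most abundant genes was 64.9% to 68.5%, the opposite-strand share 18.1% to 20.1%, the Mir208a to Mir208b ratio 26.3 to 33.9 and the copy difference 0.599 to 0.684. With 2 libraries such a value cannot lie more than 1 SD from their mean, so list shares without a replicate are uninformative. The number of detected genes depends on the count minimum: at least 1 count in both libraries gave 538, against 325 with at least 10. With no low-count filter the correlation was 0.985 and Spearman rho 0.895, and the cause was not tested.

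In the column that ignores strand, reads over genes annotated on both strands are ambiguous, so Mir378a, Mir126a, Mir30e, Mir191, Mirlet7e, Mir486 and Mir451a lose nearly all their counts, which changes every share. List shares there were 0.929% for cardiac muscle, 0.0023% for skeletal muscle, 0.00075% for endothelial, 4.72% for smooth muscle, 2.88% for fibroblast, 0.0056% for erythroid, 0.980% for leukocyte, 0.0187% for liver and gut, 0.00013% for testis X-linked, 33.9% for let-7, 2.68% for miR-30, 0.796% for miR-17-92, 0.179% for Dlk1-Dio3 and 7.92% for cardiac stress. With the most abundant gene outside the list taken from the denominator, shares were 0.815% for cardiac muscle, 0.0020% for skeletal muscle, 9.99% for endothelial, 2.51% for fibroblast, 30.3% for let-7, 3.08% for miR-30 and 0.171% for Dlk1-Dio3. Without the gene with the most opposite-strand counts, the opposite-strand share was 10.1%.

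The median log2 ratio of the cardiac muscle list was -0.27 with a sum of at least 50 counts, where fewer members are tested, and -0.29 in the column that ignores strand. That of the erythroid list was 0.86 in the column that ignores strand, where Mir451a and Mir486 are lost, and that of the fibroblast list was -0.091 with the GC trend removed. The copy difference was -0.45 in the column that ignores strand, and the cause was not tested. Among named genes, 14 of 328 log2 ratios under other settings changed direction, in 11 genes. Of these, 5 were called in the main setting: Mir126a (-0.39), Mir29a (0.018) and Mirlet7d (0.036) in the column that ignores strand, and Mir34a (-0.023) and Mirlet7b (-0.069) with total counts. Mir29a, Mirlet7d and Mirlet7b passed the test in both directions. Mir191, not called in the main setting (0.018), was called in the opposite direction with total counts (-0.103). The other 8 were called in neither setting: Mir122 (-0.085), Mir133a-1 (-0.013) and Mir223 (-0.055) with total counts, Mir122 (-0.158), Mir150 (0.022) and Mir17 (0.042) in the column that ignores strand, Mir17 (0.0032) with DESeq2 size factors and Mir191 (-0.00094) with a sum of at least 50. Over all 328, 5 lost their call and 5 gained one.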

Other observations

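In the following, the tests of carried-over stem cell RNA, GC trends and the abundance ranks of copies were chosen after the data were seen, as were the Mir302c, Mir367 and Mir205 genes.

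The Mir302 genes, which pluripotent cells express, were counted in adult heart, with 816 counts of Mir302a to Mir302d in replicate 1 and 5219 in replicate 2. If RNA carried over from stem cell libraries were the source, other genes of these cells should be counted too. Mouse pluripotent cells also express Mir367 and the Mir290 to Mir295 genes, but these 10 genes together had 9 counts, or 0.149% of the 6035 Mir302 counts. Mir367 lies beside the Mir302 genes on the same strand, so its 0 counts would be unexpected from any source and cannot tell sources apart. The low counts of the Mir290 to Mir295 genes argue against carry-over only from cells that express them. Removal of a GC trend between the libraries left the median log2 ratio of the 4 genes at 2.24, against an SD of 0.730 over tested genes, which argues against that trend as the cause. Other sources of these counts stay open, and no biological explanation was tested.

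Differences of 2-fold or more between the libraries covered 49 genes, and 50.7% of tested genes had an unadjusted exact binomial p under 0.05. That test sets the spread between single libraries against counting noise, so it decides nothing about the cause of the 49. log2 ratios fell with hairpin GC content across 325 detected genes (Pearson r = -0.184, permutation p = 0.00091, adjusted p = 0.00091 over 4 correlations, Spearman rho = -0.209, permutation p = 0.00015, adjusted p = 0.0003) and across the 126 with at least 1000 counts (r = -0.316, permutation p = 0.00024, adjusted p = 0.00032, rho = -0.346, permutation p = 6e-05, adjusted p = 0.00024). Once the straight-line trend over all 325 was removed 46 of the 49 stayed at 2-fold or more, which argues against that trend as the whole cause. Genes with a shared stretch had a median absolute log2 ratio 0.046 higher than others (two-sided permutation p = 0.524), so reads of identical copies stay open, as do untested PCR noise and an untested difference between the samples.

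The shared difference of neighbouring genes kept an intraclass correlation of 0.427 (permutation p = 3e-05) once the GC trend was removed. This argues against that trend as the cause of the correlation with the Mir302 genes included. Without the Mir302 genes, and with the trend left in, the correlation was 0.195 (permutation p = 0.0237). The trend was not removed in that setting, so its part in the difference shared by the other clusters was not tested.

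Detected genes with a same-sequence copy by name made up 0 of the 20 most abundant, 1 of the 50, 12 of the 100 and 21 of the 150 most abundant genes. Fisher's exact test against the other detected genes gave p = 0.150, 0.0167, 1 and 0.403 in that order. The cutoffs were picked after the ranks were seen, and 1 of the 4 passed 0.05, so no difference is claimed.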
